A study of Mus musculus with 18 samples.

How the data were processed

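RNA was measured by sequencing in 18 libraries of 3 mouse pancreatic ductal adenocarcinoma lines, each kept for 48 h with DMSO, 2.5 µM ionomycin or 10 ng/ml TGFb, with 2 libraries in each of the 9 groups of line and treatment. RNA was extracted with an RNeasy Mini or a NucleoSpin kit. The values are raw read counts per gene symbol as deposited by the authors, with no scaling between libraries. Per the labels, the authors' processing used CASAVA, Trimmomatic 0.32, STAR and featureCounts on the mouse build mm10; the settings, the strand mode and the annotation release are not given in the sources used here. The table held 24527 entries, of which 5059 had 0 counts in all libraries. A further 26 had names turned into dates, 19 of which were tested as they stood, with at most 0.321% of the counts of a library, and none of them is named. None of the 13 mitochondrially encoded gene names of the list below was found among the entries, so these genes could not be analysed under those names.

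Library totals ran from 17591005 to 37894692 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The ribosomal RNA gene Rn45s took 0.256% to 4.11% of the counts.

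Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter filterByExpr over the 9 groups kept 13827 genes, and TMM factors scaled the libraries. Each pair of treatments was compared with a robust quasi-likelihood F test in a model of treatment and line, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Effects within lines, and a joint test on 2 degrees of freedom that the effect was equal in the 3 lines, came from a model with a mean for each group. The SE of a log2 fold change is its size divided by the square root of F. CPM are given as mean ± SD of the 3 line means. A fold against a group with 0 counts in all libraries is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% counting interval.

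Before the data were examined, 36 gene lists were fixed: epithelial, desmosome, mesenchymal, EMT factor, SMAD, ID and BMP, TGFb pathway, matrix, integrin, actin, protease, calcineurin-NFAT, immediate early, calcium handling, ER chaperone, integrated stress response, heat shock, NRF2, lysosome, G2/M, S phase, p53, cholesterol, glycolysis, oxidative phosphorylation, interferon, NF-kB, YAP and TAZ, pancreatic and gastric lineage, squamous, fibroblast, endothelial, immune, acinar, endocrine and mitochondrially encoded genes. The 32 lists with at least 5 tested members were tested with camera on limma-voom values, with a preset correlation of 0.01 between genes and adjustment over the lists; camera with an estimated correlation and fry were alternatives. List medians come from edgeR, but those given with libraries left out, and those of the stress list with the length offset, come from limma-voom values. The named genes were also chosen by a rule fixed then: per contrast the 8 largest rises and 8 largest falls with an adjusted p under 0.05, the same sign in 3 lines and a mean of at least 2 CPM, up to 2 rising and 2 falling members per list with the smallest p, a panel of EMT, TGFb and calcium genes, and the 4 genes with the smallest p for line dependence per treatment. The text names only part of the genes that met this rule, and the others are not reported here.

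The alternatives fixed then were median-ratio (RLE) factors, library totals, no low-count filter, DESeq2, limma-voom, no line term, a mean per group, summed duplicates, a log2 fold change of at least 1, the libraries of the contrast or line alone, and leaving out each line and each library. An offset that removes each library's trend on transcript length, leaving out 4 libraries rich in short transcripts (r under -0.2 with length), and leaving out Rn45s were chosen after seeing the data. The groups share no library numbers, so no paired analysis was possible. The ionomycin and TGFb contrasts share their DMSO libraries, so their similarity was set against 20 simulations of unchanged groups and 8 splits of the DMSO libraries; the simulation was changed to redraw the controls after its first output was seen. Calls were also counted in 60 of the 108 splits of the libraries within lines.

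Data of 13827 genes were simulated with the spread between the duplicates of these libraries. The genes were drawn independently and with no trend on transcript length, so the rates below need not hold for the real libraries. For the test over 3 lines the effects were equal in each line. On these data that test found 52% of 1.5-fold, 88% of 2-fold and all 50 of the 4-fold changes for ionomycin against DMSO, with 5.03% false calls. Within PD454 it found 10% of 1.5-fold, 50% of 2-fold and 96% of 4-fold changes. The test of line dependence found 16% of 2-fold and 90% of 4-fold differences, with 7.41% false calls. Camera called 10 of 10 shifted lists and 0 of 310 unshifted lists in that simulation. In other splits of the real libraries it called a median of 9, 10 and 9 lists for ionomycin, TGFb and ionomycin against TGFb. Many of those splits keep the real groups whole in some lines and so carry part of the treatment effect.

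Positions come from GENCODE vM21 on mm10, matched by symbol, which held 13494 (97.6%) of the tested genes. Exons of Ccna2, Fn1, Has2, Ltbp3, Zeb1, Zeb2 and Zyx overlap a tested gene on the opposite strand, over at most 12.5% of their length, and the strand mode is not given in the sources used here. Ugt1a6a and Ugt1a6b share exons with each other and with other tested genes, so their counts are uncertain.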

Results

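Gene expression was measured by RNA-seq in 3 mouse pancreatic ductal adenocarcinoma cell lines, PD454, PD7591 and PD883. Each line was kept for 48 h with the vehicle DMSO, with 2.5 µM ionomycin, an ionophore that carries calcium across membranes, or with 10 ng/ml TGFb, a cytokine that drives epithelial-mesenchymal transition (EMT) in many carcinoma cells. Each of the 9 groups of line and treatment held 2 libraries, which gave 6 libraries per treatment and 18 in all. Total counts ran from 17591005 to 37894692 per library. Library 12 (TGFb PD883) with 37894692 counts and library 14 (DMSO PD454) with 32693557 were the deepest. A low-count filter kept 13827 genes for testing. The labels do not say that the duplicate libraries came from separate cultures, so the spread between duplicates may be technical. The p-values over 3 lines rest on this spread and on differences between the lines in their response. Those within lines and of line dependence rest on the spread between duplicates alone.

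Treatment was the main source of variation. Component 1 of a principal component analysis held 43.3% of the variance, of which 97.3% lay between treatments, and it set the TGFb libraries apart from the others. Components 2 and 3 held 17.2% and 14.1% and separated the lines. Component 4 held 9.18%, of which 95% lay between treatments, and it separated ionomycin from DMSO. Duplicates correlated at r of 0.981 to 0.993 over log2 CPM (counts scaled to library size) across genes, and every pair differed by more than sampling noise, with chi-square per degree of freedom from 4.11 to 69.3. The duplicates also differed along transcript length. In 4 libraries, DMSO PD454 14, TGFb PD454 18, DMSO PD883 8 and TGFb PD883 12, short transcripts were over-represented, with r between transcript length and a library's deviation from the mean of -0.245 to -0.360 across genes. The other libraries ran from -0.167 to 0.323, and genes are not independent replicates. None of the ionomycin libraries was among the 4. The ribosomal RNA gene Rn45s took 0.283% to 2.26% of the counts with DMSO, 0.304% to 4.11% with ionomycin and 0.256% to 1.04% with TGFb.

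**Figure D1:**
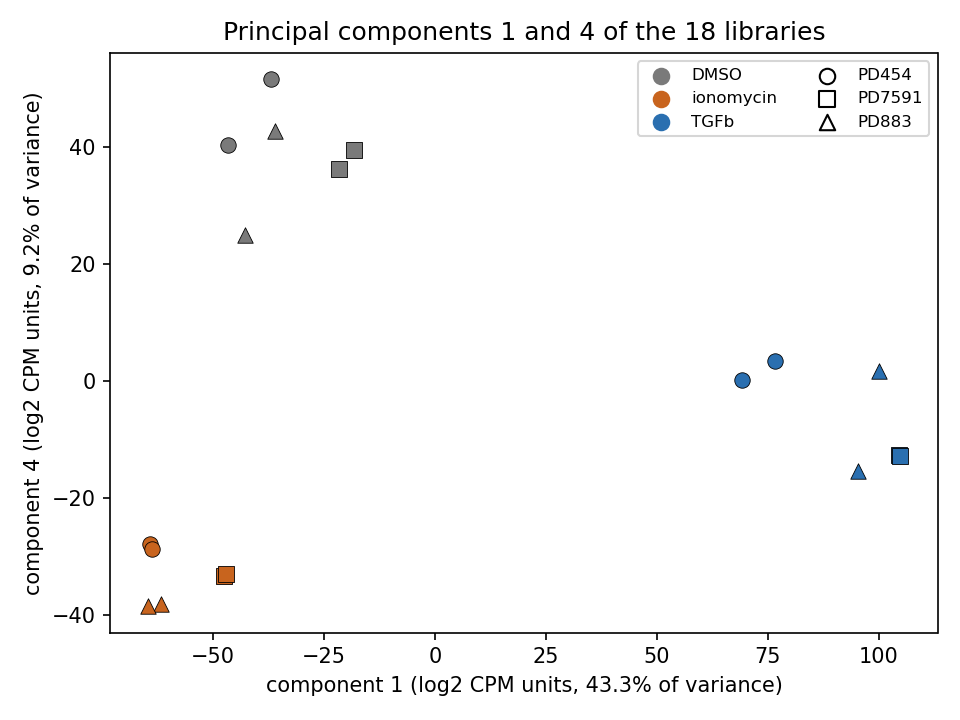
Each point is 1 of the 18 libraries, placed by its score on principal component 1 (x axis) and component 4 (y axis), in log2 CPM units; colour gives the treatment and shape the cell line. The TGFb libraries lie at high component 1 scores, between 69.2 and 105, and the ionomycin libraries lie below 0 on component 4 while the DMSO libraries lie above it.

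The comparison of ionomycin with DMSO asked how gene expression differed in carcinoma lines kept with a calcium ionophore. Genes of the integrated stress response rose with ionomycin as a list, and of the 32 lists tested it alone also passed with an estimated correlation between genes (adjusted p = 0.0366). Epithelial junction genes did not fall as a group. The epithelial cadherin Cdh1 stood at 580 ± 34.9 CPM with ionomycin and 608 ± 37.4 CPM with DMSO (mean ± SD of the 3 line means), a log2 fold change of -0.09 ± 0.27 (SE, adjusted p = 0.829). The EMT transcription factor Snai2 rose from 9.43 ± 0.968 to 26.0 ± 8.92 CPM, a log2 fold change of 1.43 ± 0.21 (adjusted p = 6.81e-05) that was positive in each line.

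In total 4599 of the 13827 genes passed the test for ionomycin against DMSO, 2372 higher and 2227 lower (edgeR quasi-likelihood test with the line as a block, Benjamini-Hochberg adjusted). With library totals in place of composition factors 4931 genes passed and 1936 of them were higher, a share of 39.3% against 51.6%. That scaling moved the median of all genes to -0.117 on the log2 scale for this contrast and to -0.108 for ionomycin against TGFb. When each line gave 1 summed sample per treatment 1858 genes passed. Of the 4599 genes, 4368 (95%) had the same sign of effect in all 3 lines.

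The integrated stress response list, targets of the transcription factor ATF4, moved most evenly. Of 24 tested members 23 rose and none fell (23 adjusted over the list alone; median log2 fold change 1.18, camera adjusted p = 2.72e-17 and adjusted p = 0.0366 with an estimated correlation). Cth, which makes cysteine from cystathionine, rose by 3.21 ± 0.21 on the log2 scale (adjusted p = 1.53e-08) and Chac1, which degrades glutathione, by 2.05 ± 0.15 (adjusted p = 2.29e-08), each in all 3 lines. Of 23 genes for endoplasmic reticulum (ER) chaperones and the unfolded protein response 16 rose and none fell (17 adjusted over the list alone; adjusted p = 2.10e-07, and adjusted p = 0.0989 with an estimated correlation). Among them were the ER stress sensor Atf6 (log2 fold change 1.62 ± 0.13) and the ER co-chaperone Dnajb9 (1.28 ± 0.14).

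Lysosome and autophagy genes rose in 18 of 25 cases and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 2.21e-09, and adjusted p = 0.0681 with an estimated correlation). The Rag GTPase gene Rragd rose by 2.93 ± 0.20 and the lysosomal hexosaminidase subunit gene Hexa by 1.62 ± 0.15 on the log2 scale. Tfeb, which encodes a transcription factor of lysosomal genes, fell by 0.64, a call lost without line PD454 (adjusted p = 0.0536) or PD883 (adjusted p = 0.101). Genes of cholesterol synthesis and its regulation fell in 22 of 25 cases and rose in none (22 adjusted over the list alone; adjusted p = 9.65e-15, and adjusted p = 0.0953 with an estimated correlation). The sterol dehydrogenase Nsdhl fell by 1.42 on the log2 scale (adjusted p = 1.24e-07).

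Among 24 calcium handling genes 14 rose and 3 fell (the same numbers adjusted over the list alone; adjusted p = 0.00165, and adjusted p = 0.0988 with an estimated correlation). The ER calcium pump Atp2a3 (SERCA3) rose from 14.6 ± 7.87 to 297 ± 91.2 CPM, a log2 fold change of 4.45 ± 0.30 (adjusted p = 1.54e-08). Atp2a2 (SERCA2) rose by 0.72 ± 0.09, while the calmodulin gene Calm3 fell by 0.53. The list for NFAT and the calcium-dependent phosphatase calcineurin holds NFAT genes themselves besides targets. It shares Egr and Nr4a genes with the immediate early list. Of its 15 tested genes 8 rose and 2 fell (8 and 2 adjusted over the list alone). Its call (camera adjusted p = 0.0140, and 0.291 with an estimated correlation) was lost without line PD454 (adjusted p = 0.142). Rcan1, a calcineurin inhibitor that calcineurin signalling itself induces, rose by 2.77 ± 0.30 (adjusted p = 2.19e-06), and Nfatc2 fell by 1.6. Immediate early genes rose in 16 of 26 cases and fell in none (17 adjusted over the list alone; adjusted p = 1.80e-06, and adjusted p = 0.291 with an estimated correlation). Klf4 rose by 0.96 ± 0.13 and Fos by 2.52 ± 0.35.

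Of 32 tested genes for epithelial junctions and identity 13 rose and none fell (15 adjusted over the list alone; median log2 fold change 0.37, adjusted p = 0.00290, and adjusted p = 0.281 with an estimated correlation). The claudin gene Cldn3 (3.20 ± 0.33), the epithelial transcription factor Grhl1 (2.34 ± 0.23) and the tight junction gene Ocln (1.49 ± 0.37) were among those that rose. The call of Ocln was lost without line PD7591 (adjusted p = 0.0803). Besides Cdh1, the keratin Krt19 (-0.07 ± 0.32, adjusted p = 0.879), Epcam (0.31 ± 0.19, adjusted p = 0.222) and Cldn7 (0.08 ± 0.52, adjusted p = 0.924) did not pass the test. Cldn7 turned to -0.00 with library totals and to -0.13 with limma-voom. Esrp1 was below the count filter. In the desmosome list 2 of 10 genes rose (2 adjusted over the list alone; adjusted p = 0.136, but 0.0263 without line PD883).

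Mesenchymal markers went both ways, with 2 of 17 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.659). Tenascin C (Tnc, 2.01 ± 0.55) and the integrin Itga5 (0.38 ± 0.11) rose, and Sparc (-1.01 ± 0.29) and the neural cadherin Cdh2 (-0.47 ± 0.17, adjusted p = 0.0383) were among those that fell. The calls of Itga5 were lost without PD454 (adjusted p = 0.156) or PD7591 (0.0562), of Sparc without PD7591 (0.110) or PD883 (0.194), of Tnc without PD454 (0.0668) or PD7591 (0.126), and of Cdh2 without PD7591 (0.514) or PD883 (0.193). The call of Cdh2 was also lost on leaving out any of 7 libraries, DMSO PD7591 1 (adjusted p = 0.0824) or 2 (0.0988), ionomycin PD7591 3 (0.0860) or 4 (0.0874), DMSO PD883 7 (0.0725) and ionomycin PD883 9 (0.0900) or 10 (0.0774). That of Tnc was lost without ionomycin PD7591 3 (adjusted p = 0.0672). Vimentin (Vim, 0.38 ± 0.18, adjusted p = 0.103) and fibronectin (Fn1, 0.45 ± 0.26, adjusted p = 0.197) did not pass the test, but passed it without DMSO PD883 7 (adjusted p = 0.00896 and 0.0229). Vim also passed without line PD883 (0.00179) and with a mean per group (0.0130). Smooth muscle actin (Acta2) stood at -0.42 ± 0.59 (adjusted p = 0.609) and was close to the detection limit, at 0.469 and 0.456 CPM. With DMSO the mean CPM of Tnc was lower still, so its rise started close to the detection limit.

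Of 11 EMT transcription factors 4 rose and none fell (4 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.120, but 0.00144 with fry). Besides Snai2, the factors that rose were Hmga2 (0.70 ± 0.13), Zeb2 (0.82 ± 0.20) and Twist1 (0.46 ± 0.11). The calls of Zeb2 and Twist1 each needed a line, PD454 for Zeb2 (adjusted p = 0.0836 without it) and PD7591 for Twist1 (adjusted p = 0.0844 without it). Zeb1 (0.06 ± 0.14, adjusted p = 0.769, and -0.02 with library totals or a length offset), Snai1 (-0.47 ± 0.39, adjusted p = 0.359, but 0.0158 without line PD454) and Prrx1 (0.49 ± 0.31, adjusted p = 0.231) did not pass.

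Targets of TGFb signalling did not move as a group with ionomycin. Of 18 SMAD-responsive genes 4 rose and 3 fell (the same adjusted over the list alone; median -0.01, adjusted p = 0.921). Ltbp3, Ctgf, Tgif1 and Smurf1 rose, and Pmepa1 (by 0.60 on the log2 scale), Ldlrad4 and Cdkn2b fell; Tgif1, Smurf1, Ldlrad4 and Cdkn2b were named after their values were seen. The call of Tgif1 was lost without DMSO PD454 13 (adjusted p = 0.0531), DMSO PD883 8 (0.0540), ionomycin PD883 9 (0.0749), the 4 libraries rich in short transcripts (0.0967), line PD454 (0.177) or line PD883 (0.184), and with no low-count filter (0.0534). Smad7 (-0.00 ± 0.28, adjusted p = 0.996, a value whose sign depended on the scaling) did not pass. Among ID and BMP targets 1 of 8 fell, Id2 by 0.98 (1 adjusted over the list alone; adjusted p = 0.130). Of 17 TGFb pathway components 5 rose (5 adjusted over the list alone; adjusted p = 0.497), among them the type I receptor Acvr1b (1.18 ± 0.13) and Bmp2 (1.73 ± 0.30).

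Around the cell, 10 of 18 protease and inhibitor genes rose with ionomycin and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 1.66e-04, and adjusted p = 0.0681 with an estimated correlation). The collagenase Mmp13 rose from 0.599 ± 0.447 to 106 ± 98.6 CPM, a log2 fold change of 7.5 ± 0.54 (adjusted p = 2.29e-08). The stromelysin Mmp3 had 3 counts over the 6 DMSO libraries and 1599 over the 6 ionomycin libraries, a ratio of 559.6 with an exact 95% counting interval of 191.2 to 2717. The ratio was 348.8 without ionomycin PD7591 3 and 330.3 without ionomycin PD7591 4, and the 3 counts lay in DMSO PD7591 1, without which it was at least 481.3. Most of the 1599 counts lay in PD7591, with 823 left without ionomycin PD7591 3 and 800 without ionomycin PD7591 4. Few lay in the other lines, with 1588 and 1590 left without ionomycin PD454 15 and 16, and 1597 without ionomycin PD883 9 or 10. The ratio thus mainly describes PD7591, and PD454 and PD883 had no DMSO counts for a fold of their own. In the extracellular matrix list 8 of 33 genes rose and 3 fell (the same adjusted over the list alone; adjusted p = 0.244), with the collagens Col18a1 at 1.37 ± 0.12 and Col6a2 at 3.47 ± 0.36. Integrins rose in 4 of 12 cases (4 adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.477 with an estimated correlation), among them Itga2 (1.08 ± 0.20). That list's call was lost without library DMSO PD454 14 (adjusted p = 0.0952), without line PD454 (0.148) and without the 4 libraries rich in short transcripts (0.138). Actin and contractile genes did not pass as a list, with 2 of 18 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.756).

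Of 28 genes for S phase and replication 13 fell with ionomycin and none rose (18 fell and 1 rose adjusted over the list alone; adjusted p = 1.66e-04, and adjusted p = 0.657 with an estimated correlation). The DNA ligase gene Lig1 fell by 0.78 and the uracil glycosylase Ung by 1.47. Of 22 G2/M genes 1 fell (0 adjusted over the list alone; adjusted p = 0.756, but 1.99e-04 without line PD883). Targets of p53 rose in 10 of 22 cases and fell in 2 (the same adjusted over the list alone; adjusted p = 0.0287, and adjusted p = 0.0953 with an estimated correlation). Gdf15, which the integrated stress response list also holds, rose by 2.48 ± 0.25. Without line PD454 the list of p53 targets no longer passed (camera adjusted p = 0.135).

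The other tested lists did not pass with ionomycin. NRF2 targets, genes of the oxidative stress response, had 5 of 15 higher, Hmox1 (1.62 ± 0.27) among them, and 3 lower (adjusted p = 0.387). NF-kB and inflammatory genes had 7 of 24 higher and 7 lower (7 and 8 adjusted over the list alone; adjusted p = 0.226), with the chemokine Ccl20 at 2.86 ± 0.21 and Csf1 falling by 1.12. YAP and TAZ targets had 5 of 16 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.119, but 0.0115 without line PD7591), with the ectonucleotidase Nt5e at 3.97 ± 0.28. Genes of the pancreatic and gastric lineage had 3 of 20 higher and 5 lower (adjusted p = 0.756), with Anxa10 at 3.19 ± 0.36 and Vsig1 falling by 1.16. Heat shock genes had 1 of 11 higher and 3 lower (adjusted p = 0.311), glycolysis and hypoxia 3 of 26 higher and 4 lower (adjusted p = 0.791). Interferon-stimulated genes had 3 of 24 higher and 4 lower (adjusted p = 0.791), and oxidative phosphorylation 0 of 25 higher and 2 lower (adjusted p = 0.244). Adjusted over the list alone, 0 oxidative phosphorylation genes passed, and the counts of the NRF2, lineage, heat shock, glycolysis and interferon lists were the same. With fry, which asks whether a list moves 1 way on balance and not whether it differs from other genes, the ID and BMP (adjusted p = 0.00284), NF-kB (0.00948), YAP and TAZ (0.0463), desmosome (0.0441), endothelial (0.00425) and heat shock (0.0441) lists also passed.

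Among markers of other cell types, 3 of 5 endothelial genes rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.226). None of 5 fibroblast or 5 squamous and basal genes passed with ionomycin, with or without adjustment over the list alone (adjusted p = 0.659 for each list). With too few tested members, 4 immune, 2 acinar and 0 endocrine genes, those marker lists were not tested.

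The largest rises with ionomycin included Srpx2, which had 0 counts in all 6 DMSO libraries. It was at least 123.9-fold higher, against a floor of 3 counts over the group (at least 74.59-fold without ionomycin PD7591 3). Most of its 354 ionomycin counts lay in PD7591, with 176 left without ionomycin PD7591 3 and 208 without ionomycin PD7591 4. Almost none lay in PD883, with 354 left without ionomycin PD883 9 and 353 without ionomycin PD883 10. The pleckstrin gene Plek rose by 7.33 ± 0.43 on the log2 scale, angiotensinogen (Agt) by 6.31 ± 0.56 (7.03 without DMSO PD454 14), the calcium-binding protein gene S100g by 5.56 ± 0.38 and Wnt7a by 5.28 ± 0.45. The largest falls included the Wnt-regulated receptor Lgr5 by 7.23, from 9.98 ± 9.26 to 0.0478 ± 0.0251 CPM (adjusted p = 1.03e-06), and the calcium/calmodulin-dependent kinase Camk4 by 3.45 (adjusted p = 1.40e-05). Each of these genes had the same sign in all 3 lines. For Srpx2 this carries no weight, since with no DMSO counts its sign could not be negative and PD883 gave almost no counts. Among the genes named here for ionomycin, summing the duplicates ended the calls of Zeb2, Tnc, Nfatc2, Twist1, Vsig1, Ctgf, Tfeb, Itga5, Sparc, Tgif1, Cdh2, Egr1, Vcam1 and Anxa8 (adjusted p from 0.0511 to 0.214). Leaving out the line term ended those of Lig1, Tfeb, Nfatc2, Itga5, Tgif1, Zeb2, Tnc, Ocln, Cdh2, Twist1, Sparc, Vcam1 and Anxa8 (adjusted p from 0.0518 to 0.254).

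**Figure D2:**
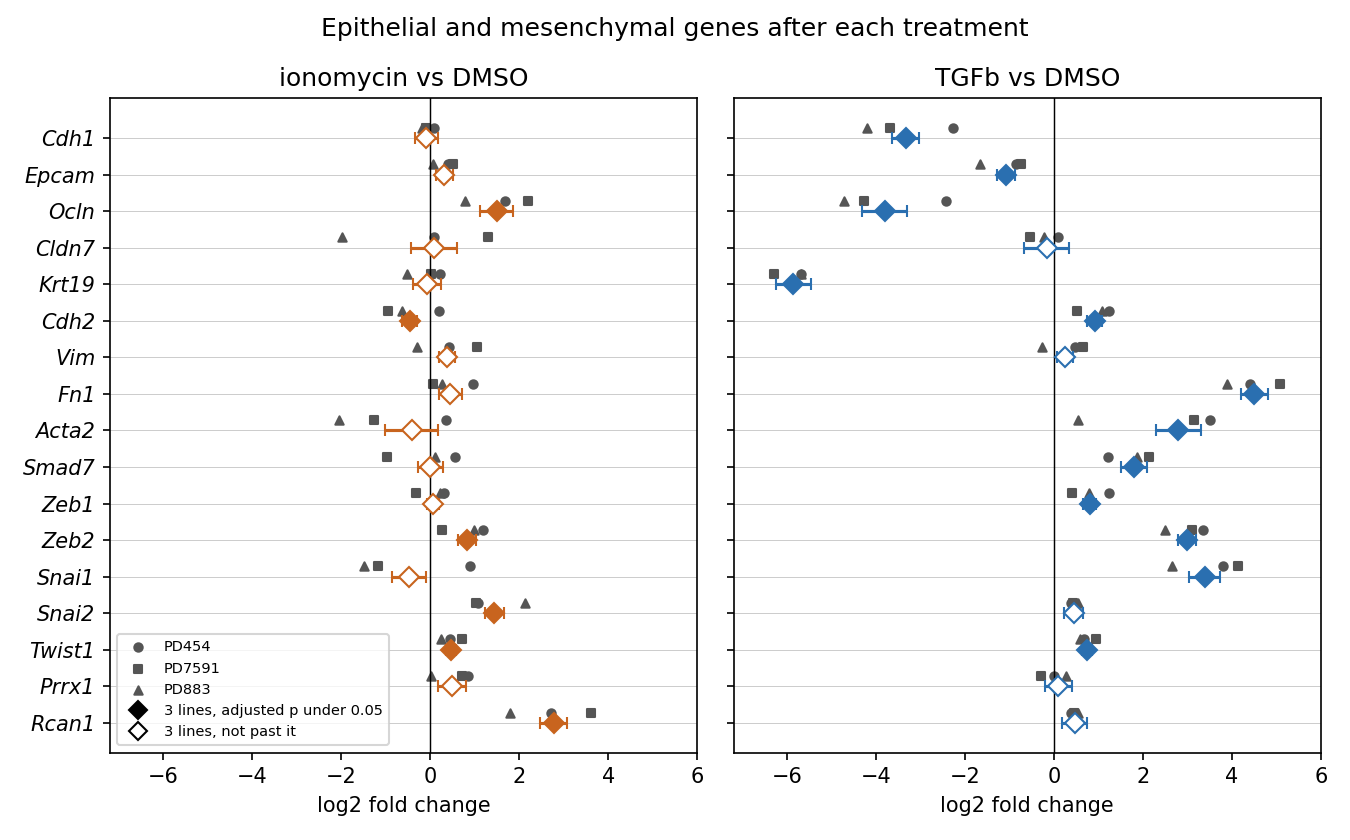
Log2 fold change against DMSO (x axis) of 17 genes fixed before the data were examined, for ionomycin (left) and TGFb (right). Diamonds give the estimate over 3 lines with its SE, filled where the adjusted p is under 0.05, and small symbols give each line. Cdh1 and Krt19 lie at -0.09 and -0.07 with ionomycin and at -3.34 and -5.86 with TGFb, while Rcan1 and Snai2 rose with ionomycin.

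The comparison of TGFb with DMSO gives the response to a known EMT inducer in the same lines. The labels do not say whether the TGFb cultures also received DMSO, so a difference in solvent cannot be told apart from TGFb here. Epithelial genes fell and mesenchymal, SMAD-responsive and protease genes rose as groups. Cdh1 fell from 608 ± 37.4 to 67.4 ± 46.8 CPM (log2 fold change -3.34 ± 0.30, adjusted p = 3.15e-08) and Krt19 from 984 ± 654 to 18.1 ± 14.2 CPM (-5.86 ± 0.40, adjusted p = 8.98e-10). Fibronectin (Fn1) rose from 288 ± 119 to 6220.3 ± 1750.5 CPM (4.50 ± 0.30, adjusted p = 9.01e-10) and Tnc from 0.372 ± 0.191 to 729 ± 759 CPM (10.76 ± 0.50, adjusted p = 6.14e-12). Each had the same sign in all 3 lines. In total 7015 genes passed, 3356 higher and 3659 lower, and 6646 of them (94.7%) had the same sign in all 3 lines. When each line gave 1 summed sample per treatment 4646 genes passed.

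Of 32 epithelial genes 23 fell with TGFb and 3 rose (the same adjusted over the list alone; median -1.59, adjusted p = 1.30e-07, and adjusted p = 0.0408 with an estimated correlation). Ocln (-3.80 ± 0.51, and -4.41 without TGFb PD454 17), the protease inhibitor Spint2 (-2.52 ± 0.16) and Epcam (-1.07 ± 0.20) fell with Cdh1 and Krt19. The claudin gene Cldn4 went the other way and rose by 9.26 ± 0.40, from 0.0941 to 60.2 CPM, and Cldn7 did not pass (-0.17 ± 0.51, adjusted p = 0.804). In the desmosome list 6 of 10 genes fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.163), with Perp falling by 2.38 and Pkp1 rising by 3.81 ± 0.21. Of 17 mesenchymal markers 12 rose and none fell (13 adjusted over the list alone; median 1.52, adjusted p = 2.28e-07, and adjusted p = 0.0408 with an estimated correlation). They included Cdh2 (0.92 ± 0.17), Acta2 (2.80 ± 0.51) and Itga5 (3.34 ± 0.12). Vim did not pass (0.25 ± 0.17, adjusted p = 0.233), but passed without library DMSO PD883 7 (adjusted p = 0.0252) or line PD883 (0.00595) and with a mean per group (0.0459).

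Of 11 EMT transcription factors 6 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.00227, and adjusted p = 0.0604 with an estimated correlation). Snai1 rose by 3.39 ± 0.35, Zeb2 by 2.99 ± 0.20, Zeb1 by 0.81 ± 0.14 and Twist1 by 0.74 ± 0.11. Snai2 (0.44 ± 0.21, adjusted p = 0.0905) passed when library DMSO PD7591 2 was left out (adjusted p = 0.0331) and with a mean per group (0.0458), and Prrx1 (0.10 ± 0.31, adjusted p = 0.809) did not pass. Of 18 SMAD-responsive genes 17 rose and 1 fell (the same adjusted over the list alone; median 1.81, adjusted p = 4.05e-08, and adjusted p = 0.0416 with an estimated correlation). Pmepa1 (2.47 ± 0.12), Smad7 (1.80 ± 0.29) and the cell cycle inhibitor Cdkn2b (1.57 ± 0.10) rose, and the integrin Itgb6 fell by 3.26.

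Id1 fell by 1.80 and Id2 by 1.92 with TGFb, but the list of ID and BMP targets, with 3 of 8 lower and 1 higher (the same adjusted over the list alone), did not pass (adjusted p = 0.0505). It passed without any of 6 libraries, DMSO PD454 13 (adjusted p = 0.0450), DMSO PD7591 1 (0.0372) or 2 (0.0425), TGFb PD7591 5 (0.0408) or 6 (0.0366) and TGFb PD883 11 (0.0381). It also passed without line PD7591 (0.0179), with no low-count filter (0.0465) and with fry (3.65e-07). TGFb pathway components went both ways, 8 of 17 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.163). The activin subunit gene Inhba rose by 4.69 ± 0.25 and Tgfb1 by 1.75 ± 0.13, and the receptor gene Tgfbr2 fell by 1.44. Extracellular matrix genes rose in 23 of 33 cases and fell in none (23 adjusted over the list alone; adjusted p = 4.05e-08, and adjusted p = 0.0604 with an estimated correlation). Proteases and inhibitors rose in 14 of 18 and fell in 1 (the same adjusted over the list alone; adjusted p = 1.09e-06, and adjusted p = 0.0255 with an estimated correlation). Timp1 rose by 3.40 ± 0.17. Actin and contractile genes rose in 13 of 18 cases and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 2.96e-04, and adjusted p = 0.0888 with an estimated correlation). Caldesmon (Cald1) rose by 2.91 ± 0.17 and the myosin kinase Mylk fell by 3.42. Integrins rose in 5 of 12 and fell in 3 (the same adjusted over the list alone; adjusted p = 0.249).

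Genes of the pancreatic and gastric lineage fell in 16 of 20 cases with TGFb and rose in 2 (the same adjusted over the list alone; median -2.38, adjusted p = 5.48e-06, and adjusted p = 0.0284 with an estimated correlation). Vsig1 fell by 5.89 and Lgals4 by 5.75 (log2 fold change -6.39 without TGFb PD454 17), while Sox9 rose by 2.40 ± 0.33 and Ctse by 1.3 ± 0.23, the latter a call lost with no line term (adjusted p = 0.180). The integrated stress response list fell, with 17 of 24 lower and none higher (18 lower adjusted over the list alone; median -0.64, adjusted p = 1.00e-04, and adjusted p = 0.190 with an estimated correlation). Slc7a5 fell by 1.62 and Psat1 by 1.46. NRF2 targets fell in 11 of 15 cases and rose in 2 (the same adjusted over the list alone; adjusted p = 4.90e-04, and adjusted p = 0.0604 with an estimated correlation). The glutathione synthesis gene Gclc fell by 3.28 (adjusted p = 2.53e-12). Interferon-stimulated genes fell in 16 of 24 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 1.96e-04, and adjusted p = 0.190 with an estimated correlation). Oas3 fell by 6.60 and Stat2 by 0.91.

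G2/M genes fell in 19 of 22 cases with TGFb and rose in none (19 adjusted over the list alone; adjusted p = 1.28e-05, and adjusted p = 0.424 with an estimated correlation). The proliferation marker Mki67 fell by 1.49 and the cyclin gene Ccna2 by 1.26. S phase and replication genes fell in 9 of 28 (8 adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.701 with an estimated correlation). The S phase call was lost without any of 5 libraries, DMSO PD454 14 (adjusted p = 0.0803), TGFb PD454 17 (0.0747), DMSO PD7591 1 (0.0694), DMSO PD883 8 (0.0895) and TGFb PD883 11 (0.0775). It was also lost with fry (0.0868) and without line PD7591 (0.0910) or PD454 (0.234), where the median by limma-voom was -0.12 against -0.27 with all lines. Cholesterol synthesis genes fell in 16 of 25 (18 adjusted over the list alone; adjusted p = 7.72e-04, and adjusted p = 0.446 with an estimated correlation). Genes of the calcineurin-NFAT list rose in 9 of 15 cases and fell in none (9 adjusted over the list alone). Its camera adjusted p was 0.00310, and 0.179 with an estimated correlation. Ptgs2 rose by 3.14 ± 0.25, whereas Rcan1 did not pass (0.47 ± 0.28, adjusted p = 0.173).

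Further TGFb list calls were lost under some alternatives, and in each of these the median of the list kept its sign. YAP and TAZ targets, 9 of 16 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.468 with an estimated correlation), no longer passed without DMSO PD454 14 (adjusted p = 0.0516) or the 4 libraries rich in short transcripts (0.0581). Glycolysis and hypoxia genes, 15 of 26 lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.701 with an estimated correlation), no longer passed without those 4 libraries (0.0650) or without any of 6, DMSO PD7591 2 (adjusted p = 0.0708), TGFb PD7591 5 (0.0803) or 6 (0.0550), DMSO PD883 7 (0.124) or 8 (0.0805) and TGFb PD883 12 (0.131). Their call was also lost with fry (0.0948) and without line PD7591 (0.0910) or PD883 (0.276). Immediate early genes, 13 of 26 higher and 3 lower (14 and 4 adjusted over the list alone; adjusted p = 0.0376, and adjusted p = 0.673 with an estimated correlation), no longer passed with an offset for transcript length (0.0650) or without DMSO PD454 14 (0.0945), TGFb PD7591 5 (0.0803) or TGFb PD7591 6 (0.0626). Their call was also lost without line PD454 (0.0591) or PD7591 (0.0949). Where 1 library was left out and the call was lost, the median log2 fold change was -0.41 to -0.50 for glycolysis and hypoxia (-0.50 with all libraries by the same limma-voom values) and 0.30 to 0.53 for immediate early genes (0.48). Vegfa (2.26 ± 0.20) and Ier3 (2.85 ± 0.19) rose, and Ldha fell by 0.81 and Klf4 by 2.29.

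The lists that did not pass with TGFb included calcium handling, with 10 of 24 higher and 9 lower (11 and 9 adjusted over the list alone; adjusted p = 0.987). Lysosome and autophagy genes had 5 of 25 higher and 9 lower (7 and 9 adjusted over the list alone; adjusted p = 0.987). ER chaperones had 5 of 23 higher and 6 lower (adjusted p = 0.803). Atp2a3 fell by 3.70 and the plasma membrane calcium pump Atp2b4 rose by 6.19 ± 0.57. Heat shock genes had 5 of 11 higher and 2 lower (adjusted p = 0.329), p53 targets 2 of 22 higher and 9 lower (adjusted p = 0.237). The ER chaperone, heat shock and p53 counts were the same adjusted over the list alone. NF-kB and inflammatory genes had 7 of 24 higher and 11 lower (7 and 12 adjusted over the list alone; adjusted p = 0.435), with Ccl20 falling by 5.80 and Il33 by 4.27. Oxidative phosphorylation genes had 6 of 25 higher and 2 lower (4 and 1 adjusted over the list alone; adjusted p = 0.239), and passed without the 4 libraries rich in short transcripts (adjusted p = 0.0242). Of the marker lists of 5 genes each, squamous and basal had 2 higher and 2 lower (adjusted p = 0.901), fibroblast 1 and 1 (adjusted p = 0.673) and endothelial 0 and 1 (adjusted p = 0.637), the same adjusted over the list alone. With fry the TGFb pathway (adjusted p = 0.00391), desmosome (0.0415), endothelial (0.0365), heat shock (0.0114), integrin (7.17e-04) and p53 (1.16e-05) lists passed.

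The largest rises with TGFb included the hyaluronan synthase Has2 (11.76 ± 0.51, adjusted p = 2.73e-12, and 13.06 without DMSO PD454 14), the cytokine Il11 (10.31 ± 0.38) and the collagen Col5a3 (9.67 ± 0.42). Srpx2, with 0 counts in all DMSO libraries, was at least 524.7-fold higher (318.2-fold without TGFb PD7591 6). The largest falls included the glucuronosyltransferase Ugt2b34 by 8.97, the kinase Pik3c2g by 8.84 and the apolipoprotein Apoa1 by 8.25. Without TGFb PD454 18 the log2 fold change of Pik3c2g was -10.28, and without TGFb PD883 12 that of Apoa1 was -9.23. All 7 had the same sign in each line, though Srpx2, with no DMSO counts, could not have had a negative sign.

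**Figure D3:**
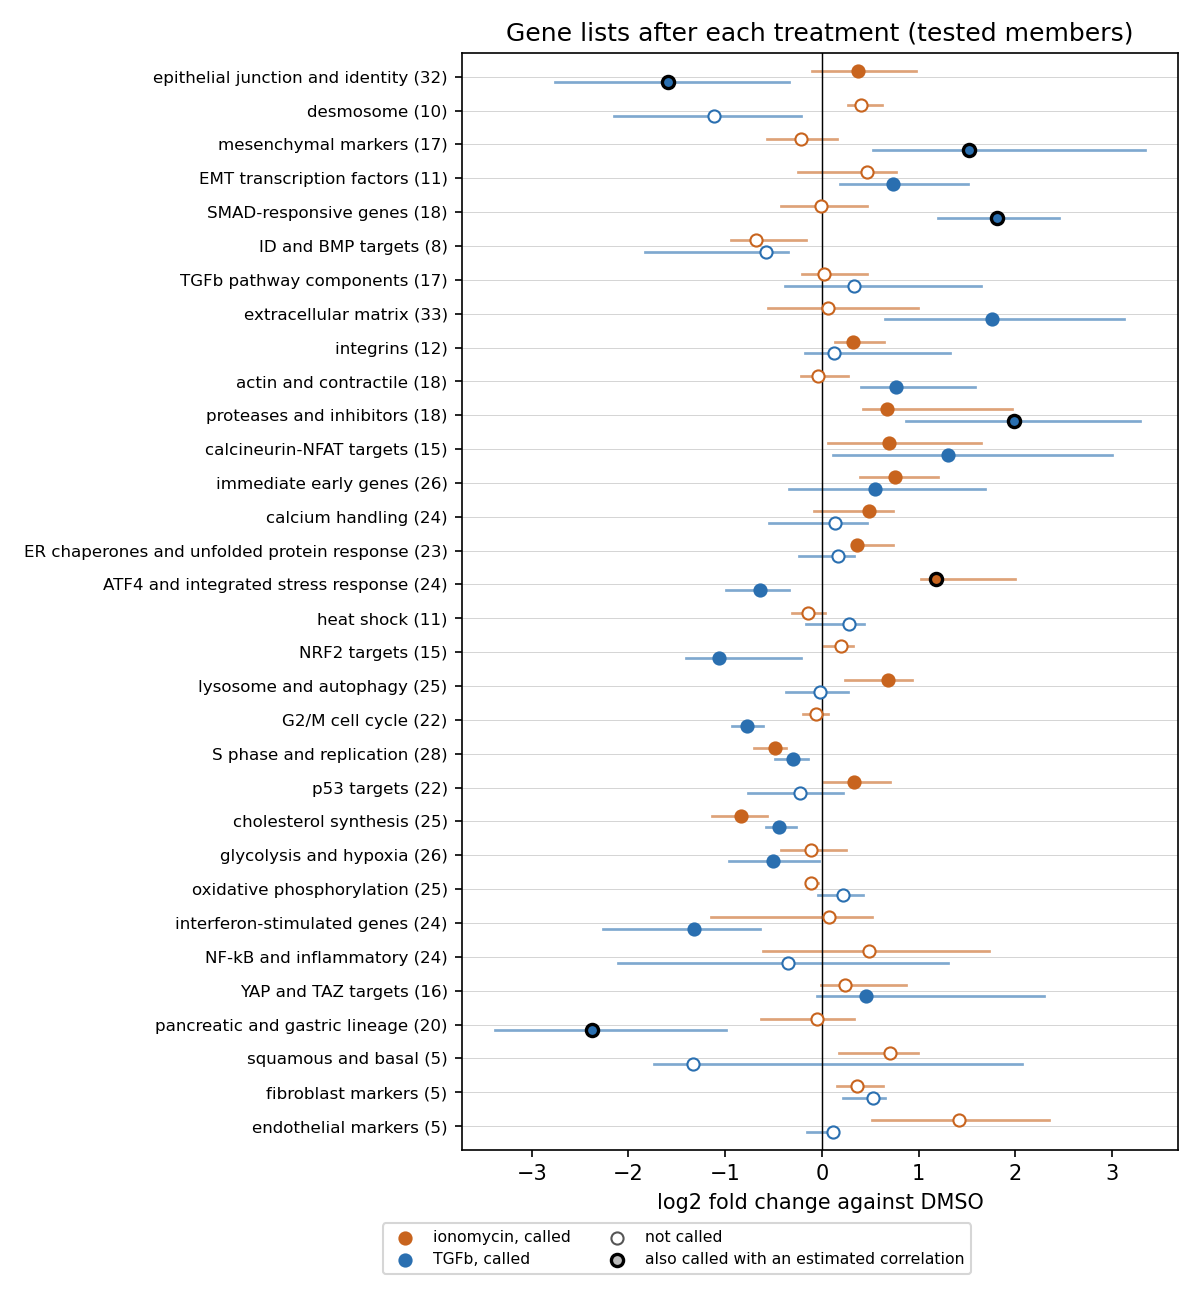
Median log2 fold change against DMSO (points, x axis) and interquartile range (lines) over the tested members of the 32 gene lists, with the number of members in brackets. Orange is ionomycin and blue TGFb, filled points passed the camera test and those with a black rim also passed with an estimated correlation. The integrated stress response list lies at 1.18 with ionomycin and -0.64 with TGFb, and the epithelial list at 0.37 and -1.59.

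Ionomycin was then compared with TGFb directly. Cdh1 was higher with ionomycin by 3.25 ± 0.29 on the log2 scale (adjusted p = 2.79e-08) and Krt19 by 5.79 ± 0.40 (adjusted p = 6.69e-10). Fn1 was lower with ionomycin, with a log2 fold change of -4.05 ± 0.30 (adjusted p = 1.85e-09). Snai1 had a log2 fold change of -3.87 ± 0.37 and Zeb2 of -2.16 ± 0.20, while Snai2 was higher with ionomycin by 0.99 ± 0.21 (adjusted p = 5.11e-04). Vim did not differ past the threshold (0.13 ± 0.17, adjusted p = 0.545). In total 8696 genes passed, 4287 higher and 4409 lower with ionomycin, and 8261 of them (95%) had the same sign in all 3 lines.

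Of the 32 lists 14 passed in this contrast, none of them with an estimated correlation. Epithelial genes were higher with ionomycin in 27 of 32 cases and lower in 1 (adjusted p = 6.29e-09, and adjusted p = 0.0655 with an estimated correlation). Mesenchymal markers were lower in 13 of 17 (adjusted p = 2.77e-06, and adjusted p = 0.0746 with an estimated correlation). All 24 integrated stress response genes were higher, Cth by 3.93 ± 0.22 and the pseudokinase Trib3 by 3.38 ± 0.20 (adjusted p = 2.54e-12, and adjusted p = 0.0655 with an estimated correlation). These counts were the same adjusted over the list alone. SMAD-responsive genes were lower in 15 of 18 cases and higher in 2 (16 and 2 adjusted over the list alone; adjusted p = 3.66e-05, and adjusted p = 0.133 with an estimated correlation). Pmepa1 stood at -3.07 ± 0.12. NRF2 targets were higher in 10 of 15 and lower in 1 (the same adjusted over the list alone; adjusted p = 9.71e-04, and adjusted p = 0.0930 with an estimated correlation). Gclc stood at 3.72 ± 0.14.

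Among the remaining lists of this contrast, pancreatic and gastric lineage genes were higher with ionomycin in 15 of 20 cases and lower in 3 (16 and 3 adjusted over the list alone; adjusted p = 2.25e-04, and adjusted p = 0.0746 with an estimated correlation). G2/M genes were higher in 17 of 22 and lower in 0 (18 and 0 adjusted over the list alone; adjusted p = 3.62e-04, and adjusted p = 0.499 with an estimated correlation) and lysosome genes in 17 of 25 and lower in 4 (19 and 4 adjusted over the list alone; adjusted p = 3.68e-04, and adjusted p = 0.241 with an estimated correlation). ER chaperones were higher in 14 of 23 and lower in 1 (14 and 2 adjusted over the list alone; adjusted p = 0.00412, and adjusted p = 0.355 with an estimated correlation), Herpud1 by 3.01 ± 0.17. Extracellular matrix genes were lower in 22 of 33 and higher in 5 (the same adjusted over the list alone; adjusted p = 2.25e-04, and adjusted p = 0.280 with an estimated correlation). Actin and contractile genes were lower in 12 of 18 and higher in 2 (the same adjusted over the list alone; adjusted p = 0.00475, and adjusted p = 0.241 with an estimated correlation). Targets of p53 were higher in 12 of 22 and lower in 4 (adjusted p = 0.0305, and adjusted p = 0.0930 with an estimated correlation), a call lost without line PD454 (adjusted p = 0.0640). The calls of cholesterol synthesis, lower in 15 of 25 and higher in 3 (adjusted p = 0.0101, and adjusted p = 0.499 with an estimated correlation), and of interferon-stimulated genes, higher in 15 of 24 and lower in 3 (adjusted p = 0.00888, and adjusted p = 0.365 with an estimated correlation), were lost without line PD7591 (adjusted p = 0.0879 for each). Those last 3 lists had the same counts adjusted over the list alone. The EMT factors (adjusted p = 0.0971), the proteases (0.0886), the desmosome list (0.0971) and oxidative phosphorylation (0.0967) were among the lists that did not pass. Oxidative phosphorylation passed with summed duplicates (0.0408) or without line PD883 (0.0247), ionomycin PD7591 4 (0.0492), ionomycin PD883 9 (0.0380) or TGFb PD883 11 (0.0456), while the length offset moved its median from -0.30 to 0.01 (adjusted p = 0.759). With fry the EMT factors (adjusted p = 8.92e-07), the proteases (1.30e-07), the desmosome (7.58e-04), calcium handling (3.57e-07), calcineurin-NFAT (0.00257), heat shock (9.58e-05), ID and BMP (6.93e-05), NF-kB (0.00276), YAP and TAZ (0.00697) and endothelial (3.47e-05) lists also passed. By camera the YAP and TAZ list (adjusted p = 0.139) passed with the length offset (adjusted p = 0.0430) and without line PD454 (0.0126). The chemokine Ccl20 (8.66 ± 0.34) and Atp2a3 (8.15 ± 0.37) were among the genes most in excess with ionomycin, and Col5a3 (-9.14 ± 0.41) among those most in excess with TGFb.

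The responses to ionomycin and TGFb were compared across genes. Their log2 fold changes correlated at r = 0.0895 over 13827 genes, with a covariance of 0.103, and genes are not independent replicates. The responses share their DMSO libraries, and 20 simulations of unchanged groups gave a mean r of 0.504 (0.443 to 0.550). Their mean covariance was 0.0351 (0.0291 to 0.0397), and the observed covariance minus this mean was 0.0682. The simulations drew genes independently and with no trend on transcript length. The difference of 0.0682 may therefore still hold part of what the shared controls add, and no shared response is read from it. With the DMSO libraries split between the contrasts, the mean r over 8 splits was 0.0344 (-0.0607 to 0.0849) and the mean covariance 0.0376 (-0.0793 to 0.0994), a range that includes 0. Of the genes that passed in both, 661 rose with each treatment and 625 fell with each, where lists drawn independently would share 575.7 and 589.3. A further 785 rose with ionomycin and fell with TGFb and 539 did the reverse, against 627.7 and 540.5. With the controls split a mean of 391 genes rose with each treatment and 385.3 fell with each. Each contrast then had fewer DMSO libraries, which by itself lowers the number of calls. These counts therefore do not show how much of the overlap came from the shared controls.

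Responses were also compared between lines. Within lines, ionomycin changed 2909 genes in PD454 (1618 higher), 2568 in PD7591 (1543 higher) and 3112 in PD883 (1599 higher), and TGFb changed 4282, 5230 and 5312. With library totals the ionomycin counts were 3062 in PD454 (1381 higher) and 3123 in PD883 (1219 higher). Log2 fold changes with ionomycin correlated between lines at r of 0.486 to 0.575 across genes, and those with TGFb at 0.704 to 0.781. A joint test of line dependence passed for 358 genes with ionomycin and 727 with TGFb. With ionomycin, Jun had log2 fold changes of 2.04 in PD454, -1.46 in PD7591 and 0.15 in PD883 (adjusted p = 4.51e-04 for line dependence), and Egr1 of 2.51, 0.03 and 1.75 (adjusted p = 5.29e-04). Over all lines Egr1 rose by 1.73, a call lost with summed duplicates (adjusted p = 0.149), without line PD454 (0.133) and without the 4 libraries rich in short transcripts (0.0585). Jun did not pass (adjusted p = 0.463), but passed without line PD7591 (0.0234). The annexin Anxa8 rose most in PD7591 (0.76, 3.07 and 0.93 in the same order, adjusted p = 4.51e-04) and the adhesion molecule Vcam1 fell most in PD883 (-0.54, -1.0 and -3.32, adjusted p = 5.29e-04). With TGFb, the sulfotransferase Chst2 rose by 5.31 in PD454, 1.12 in PD7591 and 4.11 in PD883 (adjusted p = 4.14e-06 for line dependence), and its call over all lines was lost with no line term (adjusted p = 0.0558).

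**Figure D4:**
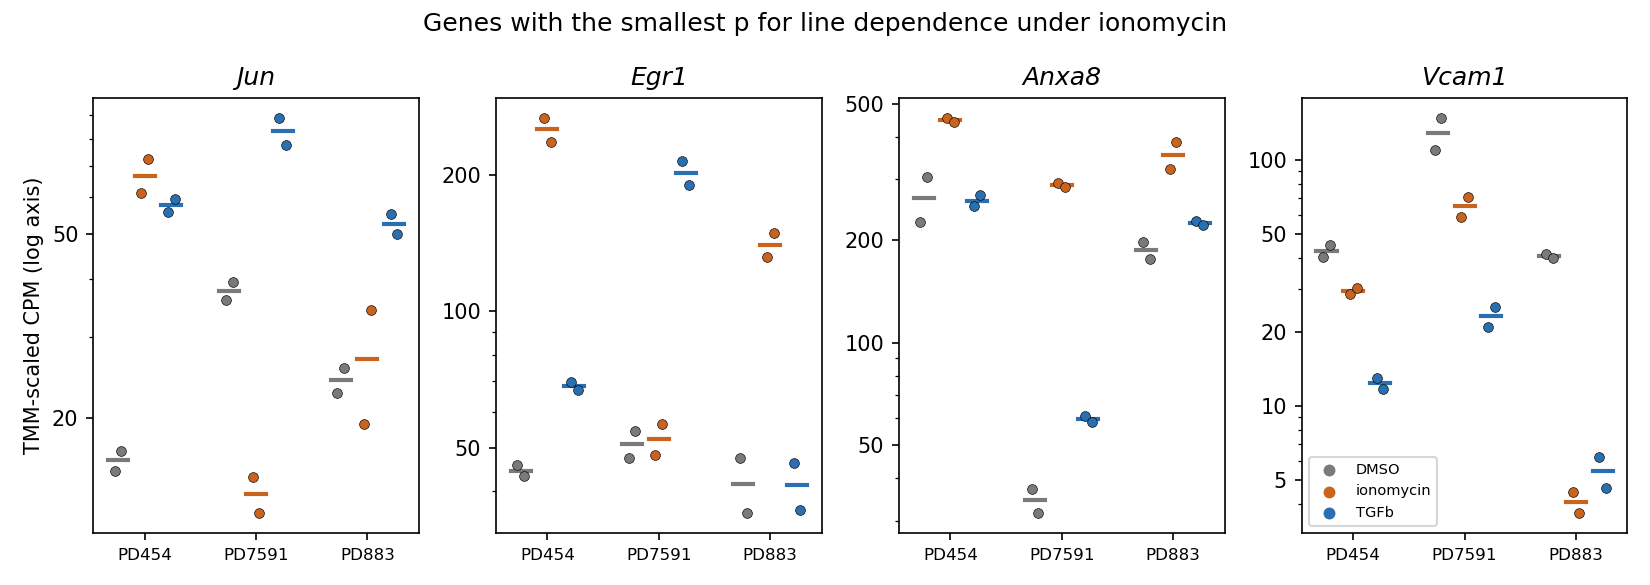
Expression of Jun, Egr1, Anxa8 and Vcam1 in TMM-scaled CPM (y axis, log scale) by cell line, with 1 point per library and a bar at the mean of 2; grey is DMSO, orange ionomycin and blue TGFb. Both ionomycin libraries of PD454 lie above their DMSO libraries for Jun, and both of PD7591 lie below theirs.

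Several of the named genes are placed here for reference, by mm10 coordinates of the GENCODE vM21 annotation, in which each is protein-coding. Cdh1 lies on chromosome 8 at 106603351 to 106670246 (plus strand), Snai2 on chromosome 16 at 14705852 to 14709385 (plus), Rcan1 on chromosome 16 at 92391953 to 92470867 (minus). Atp2a3 lies on chromosome 11 at 72961169 to 72993044 (plus), Cth on chromosome 3 at 157894248 to 157925077 (minus), Fn1 on chromosome 1 at 71585520 to 71653200 (minus) and Jun on chromosome 4 at 95049034 to 95052222 (minus).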

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

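The tests of a transcript length trend and of the 4 libraries rich in short transcripts were chosen after the results were seen. The joint test of line dependence passed for 358 genes with ionomycin and 727 genes with TGFb, each against DMSO. With ionomycin the smallest adjusted p for line dependence belonged to Jun and Anxa8 (4.51e-04 each) and to Egr1 and Vcam1 (5.29e-04 each). A transcript length trend between libraries is argued against as the whole cause of the 358, since 345 of them still passed with a length offset, among 780 genes in all. The 4 libraries rich in short transcripts stay open: 332 of the 358 passed without them, which left DMSO PD454 and DMSO PD883 with 1 library each, but 170 without DMSO PD454 14 alone. A single library stays open, since leaving out 1 of the 12 kept from 101 (without ionomycin PD454 16) to 333 (without DMSO PD883 8) of the 358. A difference between the lines themselves stays open and was not tested apart from the labels, and the labels do not say whether the duplicates came from separate cultures.

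Other genes named in the report or in the panel differed between lines by the same test. With ionomycin against DMSO the adjusted p for line dependence was 0.0489 for Agt, 0.0277 for Fos, 0.0441 for Vim and 0.0483 for Sparc. With TGFb against DMSO it was 0.0450 for Cdh1, 0.00313 for Ppl, 0.00526 for Itgb6, 0.00655 for Gclc, 0.00143 for Vsig1, 0.0158 for Stard4, 0.0263 for Inhba and 0.00269 for Nt5e. The smallest with TGFb were 4.14e-06 for Chst2, 4.28e-06 for Serpinb9b and Ugt1a6a, and 4.52e-06 for Ugt1a6b, of which the Ugt1a genes share exons. For ionomycin against TGFb it was 0.00632 for Smad7, 0.0138 for Herpud1, 0.00184 for Vsig1 and 0.00317 for Cald1. The rule used here for a library far from the others needs groups of at least 4, so it was not applied to groups of 2.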

How the results depend on the processing

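The length offset, the omission of 4 libraries rich in short transcripts and the omission of Rn45s were chosen after seeing the data. The cause of the shifts below was not tested, except where fewer samples, fewer genes or a stricter threshold enter by construction. For ionomycin against DMSO 2152 genes passed with no line term, 1858 with summed duplicates and 1350 with a log2 fold change of at least 1. For TGFb 4646 passed with summed duplicates and 2936 with that minimum, and for ionomycin against TGFb 3824. Line-dependent genes with ionomycin numbered 1050 with no low-count filter, 1296 by a DESeq2 likelihood ratio test, 780 with the length offset and 1438 without the 4 libraries. With TGFb they numbered 1391, 1486 and 1109 under the former 3. In PD7591 ionomycin changed 3999 genes without the 4 libraries and 4537 from its own libraries alone, and in PD883 1131, where TGFb changed 3535. With an estimated correlation 1, 5 and 0 lists passed for ionomycin, TGFb and ionomycin against TGFb, and fry called 19 for the first and 24 for the last. The correlation of the responses was 0.232 with no low-count filter and 0.167 without PD883.

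Leaving out a library leaves an arm with 1 library, assumed to vary like the others. Counts then ran from 3779 to 4916 for ionomycin, 6384 to 7358 for TGFb and 8267 to 8762 for ionomycin against TGFb, with 11 to 12, 15 to 19 and 14 to 15 lists, and the correlation from 0.0739 to 0.154. Within lines they ran from 1031 (without DMSO 14) to 3154 in PD454, 1133 to 1656 in PD7591 and 1925 (without ionomycin 9) to 2332 in PD883 for ionomycin. PD454 gave 1285 and 1131 without ionomycin 15 and 16, and PD7591 gave 1133, 1256, 1656 and 1357 without DMSO 1 and 2 and ionomycin 3 and 4. For TGFb they ran from 3241 to 3455, 3456 (without DMSO 2) to 3766 and 3806 to 5076. Line-dependent genes ran from 101 to 688 with ionomycin: 180, 121 and 101 without PD454 libraries 14, 15 and 16, 130, 143, 213 and 156 without PD7591 libraries 1 to 4, and 192, 688 and 185 without PD883 libraries 7, 8 and 9. With TGFb they ran from 411 to 1093: 455 and 427 without PD454 libraries 14 and 17, 472, 422, 411 and 443 without PD7591 libraries 1, 2, 5 and 6, and 1093 without PD883 library 11. No named gene or list reversed past its test, and 7 genes called for ionomycin against TGFb had the opposite sign with the length offset. Of 211 named values, 18 lost their call with summed duplicates and 17 with no line term.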

Other observations

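The tests of a length trend, of the 4 libraries, of a weaker TGFb response, of TGFb signalling and of other splits were chosen after the results were seen. The adhesion receptor P-selectin (Selp) rose with ionomycin from 0.254 ± 0.177 to 7.5 ± 4.90 CPM, endothelin 1 (Edn1) fell by 3.29 on the log2 scale, and albumin (Alb) fell by 3.68, a call lost with summed duplicates (adjusted p = 0.0875). The chloride channel gene Clic5 stood at 92.6 ± 33.2 CPM with ionomycin and 0.167 ± 0.128 with TGFb. The gelatinase Mmp9 rose with TGFb from 0.05 ± 0.0248 to 17.9 ± 13.7 CPM. Leaving out DMSO PD454 14 moved its log2 fold change from 7.96 to 8.74, and leaving out TGFb PD454 17 moved that of Clic5 for ionomycin against TGFb from 9.22 to 9.97. Each of these changes had the same sign in all 3 lines.

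The integrated stress response list was higher with ionomycin (median log2 fold change 1.18) and lower with TGFb (-0.64, a call lost at adjusted p = 0.190 with an estimated correlation). A transcript length trend between libraries is argued against as the whole cause, since with the length offset the medians were 1.20 and -0.68 and the list still passed in each contrast at the preset correlation. The 4 libraries rich in short transcripts are argued against as well, since without them the medians were 1.23 and -0.57 and it passed in the same way. A response of the cells to each treatment stays open as a hypothesis, found and tested on the same data.

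It was asked whether the ionomycin response may be a weaker form of the TGFb response. Over the 107 members of the epithelial, mesenchymal, EMT factor, SMAD and matrix lists, with separate DMSO libraries, the highest r between the responses over 8 splits was -0.0551, which argues against it for these genes. TGFb signalling raised by ionomycin was tested on the SMAD-responsive genes: 4 of the 17 that rose with TGFb also rose with ionomycin and 3 fell, where 2.92 would rise by chance (one-sided Fisher's exact p = 0.331). That count gives no sign of TGFb signalling raised as a whole, and an effect on a few of its genes stays open.

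Other splits of the libraries within lines were counted, 60 of 108 with the real one included. For genes only 1 of 60, the real split, gave as many calls in each contrast. Chance is then unlikely, at a share under 0.05, if the libraries are separate samples, which the labels do not say. Calls were 4599 against at most 1305 for ionomycin and 7015 against at most 4737 for TGFb. For ionomycin against TGFb they were 8696 against at most 4000. These highest other counts came from splits that kept each pair of duplicates whole in 2 lines. Splits that mix the treatments hold the treatment effect in their spread, which lowers their calls. The other counts are therefore not the level that unchanged libraries would give. If the duplicates are technical, only the splits that keep each pair whole count, 3 besides the real one, too few for a share under 0.05; they gave at most 2, 4 and 10 genes in the same order. For the number of called lists chance is not excluded: 19 of 60 splits gave at least the real 12 for ionomycin (highest other 18), 7 of 60 the real 18 for TGFb (highest other 19) and 12 of 60 the real 14 for ionomycin against TGFb (highest other 17). The other splits called a median of 9, 10 and 9 lists. Many of them keep the real groups whole in some lines and so carry part of the treatment effect. Splits that mixed the treatments evenly in every line called at most 10, 10 and 5 lists, but they hold the treatment effect in their spread. Neither kind of split decides whether the number of called lists exceeds chance.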
